A study of Mus musculus with 130 samples.

How the data were processed

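RNA of 130 single mouse embryos was measured with Smart-seq2 libraries, 80 from embryos cultured with SR1848 and 50 from DMSO controls. Each sample's group was taken from its title in the labels, where the controls are marked NT. No title names DMSO, so the DMSO treatment of the controls was taken from outside the titles. Per the submitters' processing notes the tools named were bcl2fastq, Trim Galore 0.6.2, kallisto 0.46.1, R 3.5.1 and DESeq2 1.32.0, and the builds named were mm10 and hg19, with no role given for either. The authors deposited a table of kallisto estimated counts per transcript with 119358 entries, of which 28.5% of the values are not whole numbers. Of these entries 119353 are mouse transcripts and 5 are others: B1, B2, an entry under the Nr5a2 gene identifier and a pair of GFP entries. What sequence stands behind these 5 is not given in the sources used here. The authors also deposited a log2 table, which equals log2(count / size factor + 1) with the total count as size factor to within 5.3e-14, and was used only for that check. Another deposited table holds the authors' own DESeq2 comparison per transcript, with log2 fold changes and adjusted p-values, base means on a signal scale and a test score. Its log2 fold change is positive where SR1848 is higher: among 11261 transcripts with a base mean above 50 the sign matched the counts in 97.0%, while the sign of its test score was the opposite in 99.6% of the entries, so that score was not used.

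Estimated counts spread reads over transcripts and copies that share sequence, so members of near-identical families have uncertain values. Transcripts were assigned to genes with the identifiers of the authors' deposited table (117282 transcripts) or GENCODE M21 (345). The 1726 transcripts with no gene held 0.735% of counts and the 5 other entries 0.0258%, and these stayed out of gene tests and library sizes. Counts were summed per gene, giving 36134 genes of which 30065 had any count, and rounded to whole numbers. Coordinates are those of GENCODE M21 on mm10. Total counts per embryo ran from 2730852 to 8438537. Reads carry no molecular identifiers, so counts are not independent molecules.

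Genes were kept by filterByExpr and tested with edgeR 4.0.16 (R 4.3.3): TMM factors, estimateDisp, robust glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over 13222 genes and a threshold of 0.05. The biological coefficient of variation was 0.771. Standard errors are the absolute log2 fold change over the root of F. The values quoted in CPM use TMM-scaled library sizes, and SDs are between embryos. B1, B2 and the Nr5a2 gene-identifier entry were tested in the same model. Gene lists were tested with limma 3.58.1 camera on log2 CPM (prior count 1) with a correlation of 0.01, and again with an estimated correlation, with adjustment over the 26 lists that had at least 3 tested members. List scores, their spread, depth and detected genes were compared with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05. For detected genes, embryos were thinned to the 5th percentile of totals, which left out 6 SR1848 embryos and 1 control.

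The groups, tests, alternatives, 27 gene lists and the rule for named genes were fixed before the data were examined. The rule takes Nr5a2, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05 and a mean of at least 20 CPM (leaving out predicted Gm, Rik and unnamed genes), and from each list the 4 members with the smallest p and the most abundant member. Of the 139 genes it gives, the text names a part. An item that the rule gives is not reported here. The lists are 2-cell-stage genes, proposed genome-activation regulators, nuclear receptors, Nr5a2 targets in liver and gonad, pluripotency factors, trophectoderm genes, oocyte transcripts, the subcortical maternal complex, maternal chromatin factors, ribosomal proteins, ribosome biogenesis, translation initiation, proteasome, splicing, RNA polymerase II, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, cholesterol synthesis, p53 targets, stress response, heat shock, G2 and M phase, DNA replication, and cumulus, sperm and blood cell markers. They were written from general knowledge, not from these samples.

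Alternatives were RLE, upper-quartile and total-count scaling, no filter and a filter of 5 CPM, DESeq2 1.42.0, limma-voom, depth or detected genes as a covariate, thinning, leaving out embryos more than 3 median absolute deviations below the median depth or detected genes, the embryo number as a block, and transcripts tested one by one. Scaling to oocyte transcripts, embryo numbers up to or above 40, leaving out multigene families, and other scalings of the B1, B2 and Nr5a2 gene-identifier entries were added after seeing the data. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per gene was 18.1, where about 1 is expected of a library deposited a second time, so each embryo counts once.

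The functions were tested on simulated counts for the 13222 genes and the real library sizes, with 200 genes changed by design between groups of 80 and 50. Of the 4-fold changes 90.9% were recovered, of the 2-fold changes 76.1% and of the 1.5-fold changes 46.3%, and 2.74% of calls were unchanged genes. A simulated raised list passed each list test, and of 26 unchanged lists none passed camera and 1 passed the permutation of scores. Simulated genes varied independently of each other, so these list results do not cover real lists whose members vary together.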

Results

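Single mouse embryos of the 2-cell stage were profiled by Smart-seq2, a full-length cDNA method primed here with oligo-dT, after culture with SR1848 or with its solvent. SR1848 is a small molecule used to block Nr5a2 (LRH-1), an orphan nuclear receptor that binds DNA as a monomer. B6129F1 zygotes were collected 5 hours after fertilization, and from 6 hours they were kept in 10 µM SR1848 or in 0.1% DMSO. The series asks what Nr5a2 contributes to zygotic genome activation, the start of transcription from the embryo's own genome. A total of 130 embryos were analysed, 80 with SR1848 and 50 with DMSO, each as its own library. The design text lists 56 control embryos, and the other 6 were not analysed here. Nothing in the labels says which embryos shared a female, a culture drop or a library plate. The p-values therefore measure the spread between these embryos, part of which may be technical. They also treat the embryos as independent, which shared handling would break. Whether the groups were handled apart is not given either, so handling shared by a whole group cannot be told apart from SR1848.

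Total estimated counts per embryo ran from 2730852 to 7824458 with SR1848 (n = 80) and from 3173683 to 8438537 with DMSO (n = 50). The SR1848 mean minus the DMSO mean was -613785 counts, a difference past the threshold (adjusted p = 0.00925, permutation test, two-sided). After thinning to a common total, 15150 ± 690 genes were detected per SR1848 embryo (n = 74) and 15525 ± 383 per control (n = 49; adjusted p = 0.0015). The 100 most abundant genes took 34.9 ± 4.98% of counts with SR1848 and 24.8 ± 2.95% in controls (adjusted p = 4e-05). The share of counts on mitochondrially encoded genes was 5.42 ± 2.80% against 4.59 ± 1.91% and did not pass (adjusted p = 0.0712).

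Nr5a2 transcripts themselves were lower in the treated embryos. The gene (ENSMUSG00000026398) lies on chromosome 1, 136842571 to 136960448, minus strand, in GENCODE M21 on mm10. Its summed transcripts stood at 99.2 ± 27.7 CPM (counts scaled to library size) in the 50 controls and at 10.5 ± 7.65 CPM in the 80 SR1848 embryos, 9.41-fold lower (log2 fold change -3.23, SE 0.178, edgeR adjusted p = 1.1e-36). All 80 SR1848 embryos were below every control embryo. An inhibitor of a protein need not change its message, so this value does not check the labels.

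Treated and control embryos differed across most of the transcriptome. Of 13222 genes tested, 10861 (82.1%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 6033 higher and 4828 lower with SR1848. At least 2-fold changes were seen in 3728 and 3409 genes, and 230 rose and 559 fell at least 8-fold. In 226 genes the values of the 80 SR1848 embryos and those of the 50 controls did not overlap at all, which random grouping gives a gene with a probability of 6.7e-37. The first principal component held 30.5% of the variance and separated the groups without overlap, with SR1848 embryos between 10.9 and 131 and controls between -160 and -78.7. Relative abundances leave the total amount of mRNA open. Scaled to the summed oocyte transcripts instead of TMM (trimmed mean of M-values), a choice made after seeing the data, 3422 genes were higher and 6257 lower, so 35.4% of the changed genes were higher against 55.5% with TMM, and the median log2 fold change of all genes moved from 0.24 to -0.35.

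**Figure D1:**
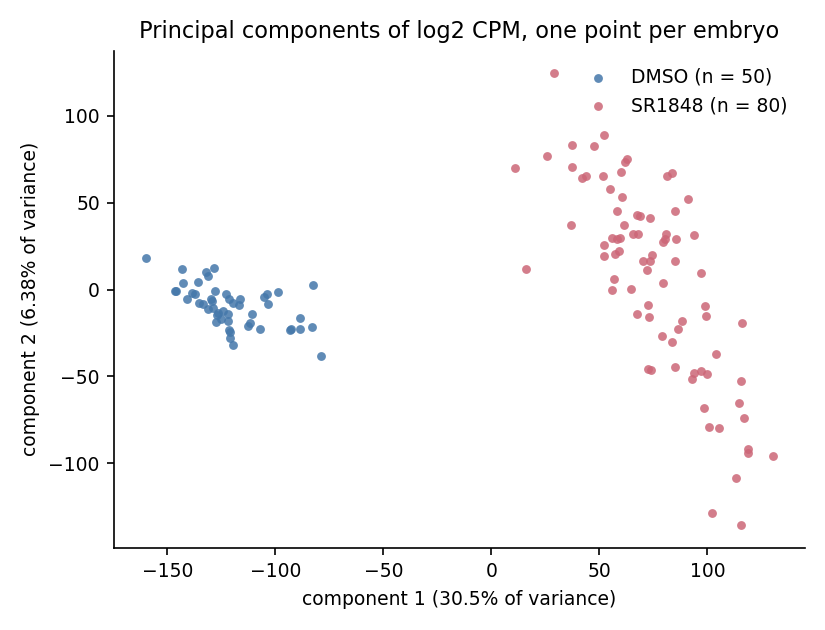
Principal components 1 and 2 of log2 CPM over the 13222 tested genes, with a point per embryo (80 SR1848, 50 DMSO). The groups do not overlap on component 1, and on component 2 SR1848 embryos range from -136 to 125 and controls from -38.0 to 18.1.

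The genes with the largest falls were nearly lost. Timd2, which encodes a cell-surface ferritin receptor (chromosome 11, 46668960 to 46707061), went from 450 ± 191 CPM in controls to 6.42 ± 5.29 CPM, 70.1-fold lower (log2 fold change -6.13, SE 0.207). Sumo2, encoding a small ubiquitin-like modifier (chromosome 11, 115523102 to 115536276), fell from 466 ± 162 to 10.6 ± 8.23 CPM. Kif3c, a kinesin motor subunit, fell 52.4-fold. Arfrp1, Npl, Iqub, Ccdc25, Rnf11 and Them4 were also among the largest falls, with log2 fold changes between -5.53 and -5.00. For each of these genes all 80 SR1848 embryos lay below every control, and the adjusted p was at most 6.2e-31.

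The largest rises were led by regulators of patterning that were close to absent in controls. Olig1, a bHLH factor of oligodendrocyte precursors (chromosome 16, 91269772 to 91271933), rose from 2.13 ± 2.89 to 158 ± 132 CPM (log2 fold change 6.19, SE 0.346, edgeR adjusted p = 6.6e-36). Hes1, a Notch-responsive repressor, rose from 8.87 ± 11.8 to 393 ± 469 CPM, and Hes6 from 6.13 ± 5.96 to 215 ± 165 CPM. The homeobox genes Msx1, Lhx6 and Dlx2 rose by log2 values of 5.19, 5.45 and 5.39, and Jun, an immediate-early gene, by 5.44. Cited4, Herpud1 and AF067061 made up the rest of the 10. The spread among treated embryos was wide: 80 of 80 SR1848 embryos lay above every control for Msx1, 77 for Olig1 and Hes1, and 56 for Herpud1.

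**Figure D2:**
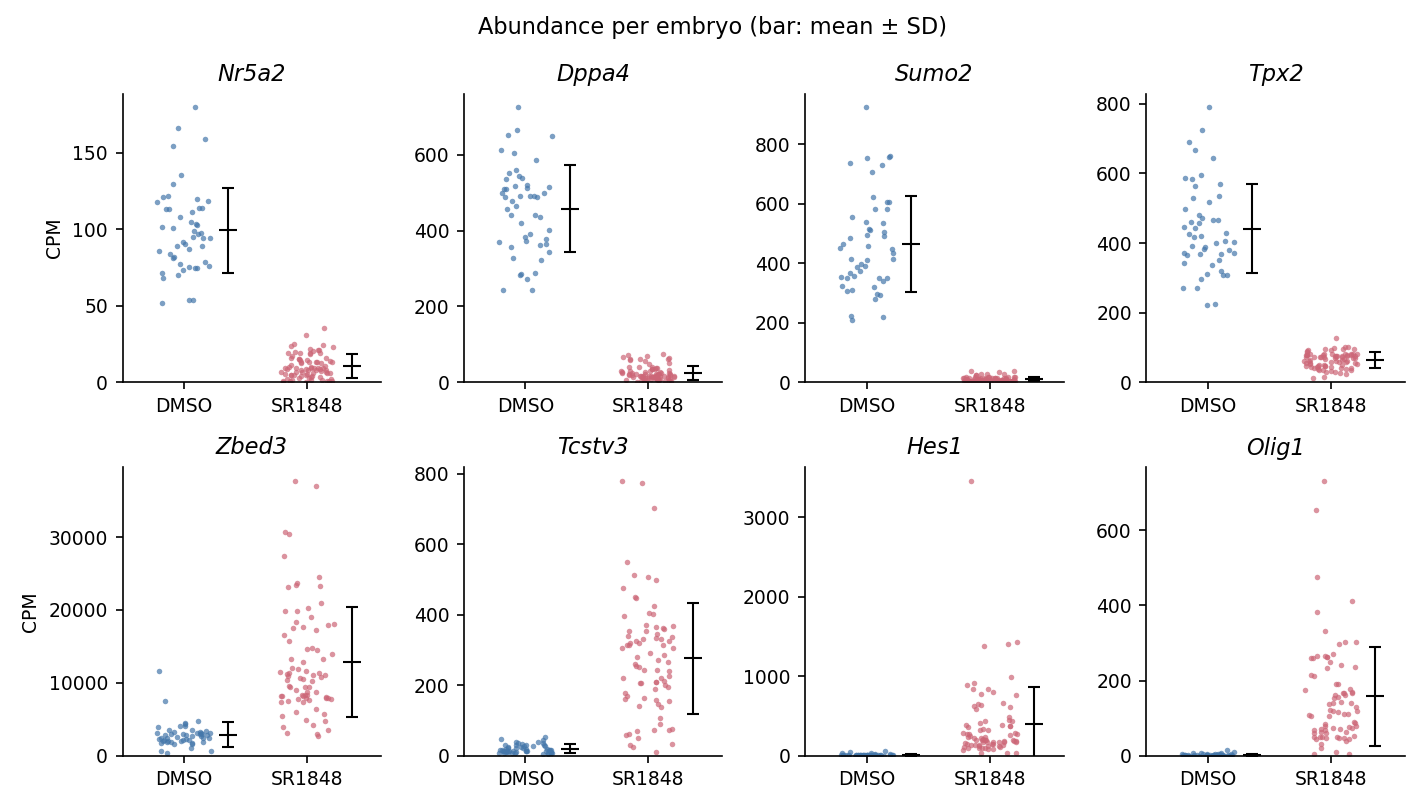
CPM per embryo of 8 genes in DMSO (n = 50) and SR1848 (n = 80) embryos on linear axes from 0; points are embryos, and bars are means ± SD, ending at 0 where the SD exceeds the mean. Nr5a2, Dppa4, Sumo2 and Tpx2 were lower with SR1848, and Zbed3, Tcstv3, Hes1 and Olig1 were higher.

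Genes known to be switched on transiently in 2-cell embryos were mostly higher with SR1848. Of 28 tested members of a list fixed before the data were examined, 22 rose, 5 fell and 1 did not pass, and the same 22 and 5 were counted when adjusted over the list alone. Tcstv3 rose from 20.1 ± 11.7 to 276 ± 159 CPM, Tcstv1 from 16.3 ± 9.64 to 242 ± 160 CPM, and Gm20767 15.7-fold. Zscan4d (log2 fold change 2.46), the homeobox gene Duxf3 (3.60) and Zfp352 (1.49), picked after their values were seen, also rose. Tmem92, the most abundant member, rose 1.39-fold, and its value turned to -0.12 on the log2 scale under the oocyte scaling. Tdpoz2, Gm16513, Sp110, Arg2 and Tdpoz1 fell. The list passed as a set with a preset correlation (camera adjusted p = 0.000416) but not with an estimated one (adjusted p = 0.37 with an estimated correlation). Many members belong to families of near-identical copies, so the division of reads within a family is uncertain. The per-embryo score, the mean log2 CPM of the members, was 1.52 higher with SR1848 (adjusted p = 1.4e-05, permutation test, whose unadjusted p of 1e-05 is the smallest it can give), and 76 of 80 embryos were above the control median.

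Factors that have been proposed to drive genome activation went mostly the other way. Of 32 tested, 20 fell, 9 rose and 3 did not pass, and the counts were 20 and 9 when adjusted over the list alone (camera adjusted p = 0.00394; adjusted p = 0.0806 with an estimated correlation). Dppa4 fell from 458 ± 115 to 24.4 ± 18.8 CPM and its partner Dppa2 from 375 ± 133 to 65.9 ± 32.3 CPM. Nfyc, a subunit of the CCAAT-binding factor NF-Y, fell 2.69-fold. Klf17, the most abundant member, stood at 1041 ± 353 against 1199 ± 264 CPM (log2 fold change -0.20, edgeR adjusted p = 0.014), a call that ended with upper-quartile factors (0.023) and under 5 other settings (-0.29 to -0.13). The list score fell by 1.28, with all 80 SR1848 embryos below every control.

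Among 20 tested nuclear receptors 12 rose, 5 fell and 3 did not pass, over all genes and adjusted over the list alone (camera adjusted p = 0.703; adjusted p = 0.769 with an estimated correlation). Under the oocyte scaling 6 rose and 6 fell, and Nr6a1 lost its call (log2 fold change 0.028). The list median was 0.63, but its mean was -0.038 and the score per embryo was -0.21, since the falls were the larger. Nr2c2 (TR4) fell 10.8-fold and Rarg 6.24-fold, while Esr2 rose 2.77-fold and Nr6a1, the most abundant, 1.48-fold. Known targets of Nr5a2 in liver and gonad did not differ detectably from other genes as a set (11 tested, 7 higher and 2 lower, also adjusted over the list alone; camera adjusted p = 0.703; adjusted p = 0.769 with an estimated correlation). Under the oocyte scaling 3 of these rose and 4 fell. Apom fell 4.47-fold, and Scarb1, Tet2 and Pou5f1 rose between 2.04-fold and 2.59-fold, a call that Scarb1 lost under the oocyte scaling (log2 fold change 0.28). Ccne1, a cyclin, fell from 700 ± 395 to 435 ± 339 CPM, a call that ended in embryos numbered above 40 (log2 fold change -0.40).

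Pluripotency genes split (23 tested, 8 higher, 13 lower, the same adjusted over the list alone; camera adjusted p = 0.28; adjusted p = 0.387 with an estimated correlation). Their score per embryo fell by 0.87 (adjusted p = 1.4e-05, permutation test), with 77 of 80 SR1848 embryos below the control median. Nanog rose from 4.56 ± 2.15 to 24.1 ± 18.1 CPM beside the falls of Dppa4, Dppa2 and Nr5a2. Tcl1, the most abundant, rose 1.75-fold but had a log2 value of -0.047 under the oocyte scaling. Trophectoderm genes split as well (16 tested, 9 higher, 3 lower, the same adjusted over the list alone; camera adjusted p = 0.222; adjusted p = 0.378 with an estimated correlation). The trophectoderm score per embryo rose by 0.52 with TMM (adjusted p = 1.4e-05, permutation test), with 69 of 80 SR1848 embryos above the control median. The score was not computed under the oocyte scaling, where 7 members rose and 3 fell. Tead4 fell from 29.4 ± 16.6 to 0.484 ± 1.77 CPM, whereas Id2 rose 9.73-fold and the keratins Krt7 and Krt18 rose 14.4-fold and 7.05-fold.

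Transcripts stored in the oocyte were higher with SR1848. Of 44 tested oocyte transcripts 36 rose, 4 fell and 4 did not pass, over all genes and adjusted over the list alone (camera adjusted p = 0.000389; adjusted p = 0.378 with an estimated correlation). Spin1 rose from 4626 ± 1646 to 11661 ± 6295 CPM, Cpeb1, which controls polyadenylation of stored messages, 3.82-fold, the germ-cell RNA-binding gene Dazl 3.16-fold and Lhx8 3.26-fold. Ccnb1, the mitotic cyclin B1, fell from 1669 ± 336 to 612 ± 227 CPM. The 12 tested members of the subcortical maternal complex list, proteins of the egg cortex, all rose with TMM and adjusted over the list alone (camera adjusted p = 0.00305; adjusted p = 0.148 with an estimated correlation), led by Zbed3 from 2888 ± 1724 to 12860 ± 7512 CPM. Under the oocyte scaling, which removes their mean shift by construction, 20 oocyte transcripts rose and 13 fell, and 3 members of the complex rose and 1 fell. Maternal chromatin factors went both ways (24 tested, 12 higher and 7 lower, also adjusted over the list alone; camera adjusted p = 0.627; adjusted p = 0.769 with an estimated correlation), and their median turned negative with total-count (-0.033; 8 higher, 9 lower) and oocyte scaling (-0.50; 5 higher, 13 lower). Dppa3 (Stella) fell 2.2-fold, Hira 4.02-fold, and Kmt2d and Npm2 rose 2.04-fold and 2.56-fold.

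The machinery for making, translating and degrading proteins fell broadly. Ribosome biogenesis had 49 of 55 members lower and 5 higher (camera adjusted p = 5.9e-11; adjusted p = 0.0547 with an estimated correlation), among them Polr1e, a subunit of RNA polymerase I (275 ± 69.9 to 14.4 ± 9.8 CPM), Imp4 6.98-fold, Nop58 8.06-fold and Ncl (nucleolin) 2.91-fold. Gtpbp4, the most abundant, rose 2.58-fold. Ribosomal protein genes had 66 of 83 lower and 6 higher, or 67 and 6 adjusted over the list alone (camera adjusted p = 2.9e-08; adjusted p = 0.381 with an estimated correlation). Rps27 fell 9.12-fold and Rps19 4.82-fold, and Rplp0 rose 1.56-fold, without a call under the oocyte scaling (log2 fold change 0.10). Translation initiation factors had 31 of 42 lower and 5 higher, or 32 and 5 adjusted over the list alone, with Eif2s1 10.7-fold lower. Proteasome subunits had 30 of 36 lower and 2 higher, with Psmb1 8.55-fold and Psma3 4.23-fold lower, and splicing factors 42 of 54 lower and 5 higher, with Lsm8 13.5-fold lower. The counts of ribosome biogenesis, proteasome and splicing genes were the same adjusted over the list alone. Initiation factors, proteasome and splicing passed with the preset correlation (camera adjusted p between 3.5e-09 and 3.3e-07) and also with an estimated one (adjusted p = 0.0432 with an estimated correlation for each). Eif5a (log2 fold change -0.017) and Psmd7 (-0.16), the most abundant members of their lists, did not pass with TMM, but Eif5a passed with total counts (-0.20) and the oocyte scaling (-0.61), and Psmd7 with these (-0.31 and -0.54) and with limma-voom (-0.39).

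**Figure D3:**
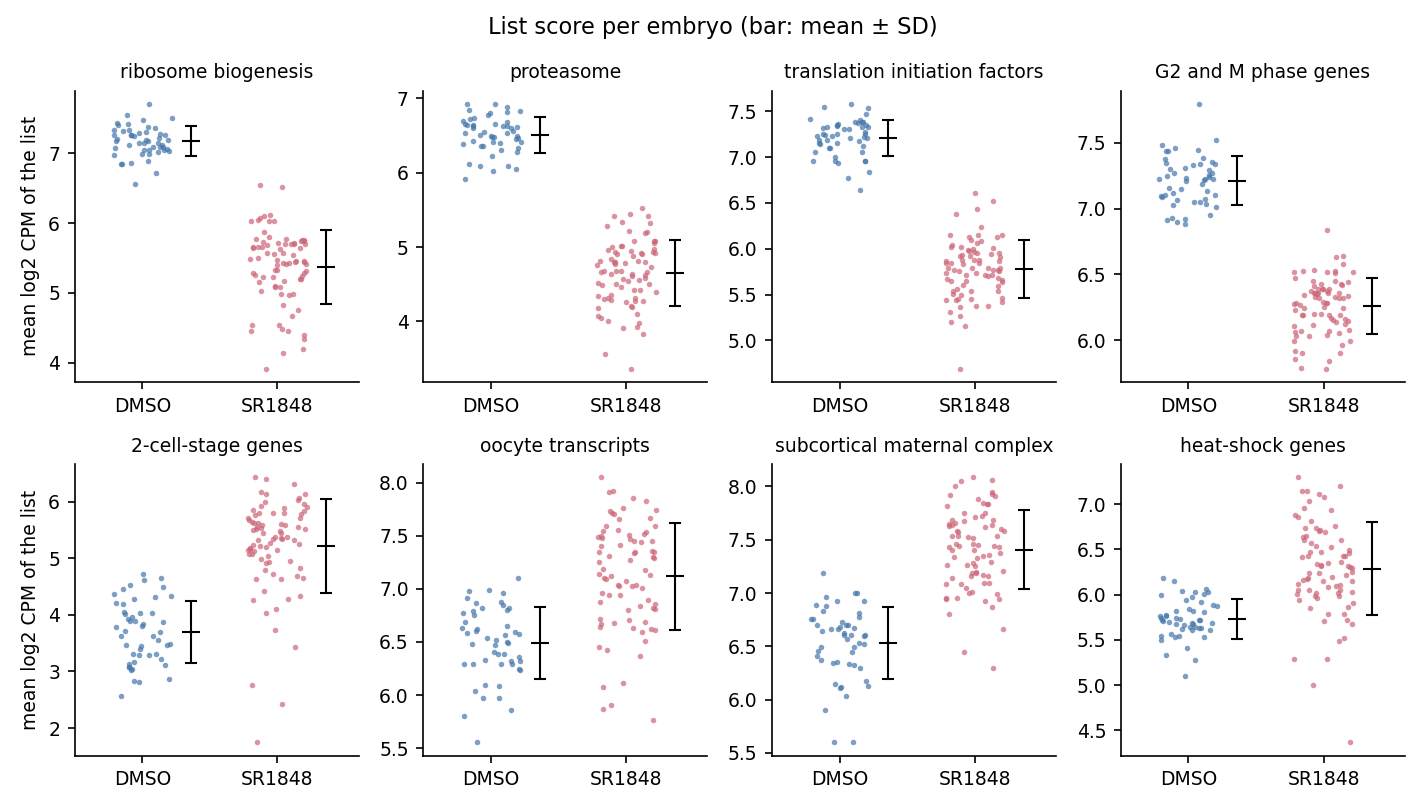
Score per embryo (mean log2 CPM over the tested members) of 8 gene lists in DMSO (n = 50) and SR1848 (n = 80) embryos; points are embryos and bars are means ± SD. The SR1848 embryos lie below every control in the 4 upper panels and are on average higher in the 4 lower panels.

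RNA polymerase II subunits and its general and Mediator factors were lower in 48 of 72 cases and higher in 14, also adjusted over the list alone (camera adjusted p = 0.000389; adjusted p = 0.0547 with an estimated correlation). Med29 fell 13-fold and Polr2e 5.66-fold, and Polr2c, the most abundant, rose 1.97-fold. Genes for G2 and mitosis fell in 22 of 30 cases and rose in 5, or 22 and 6 adjusted over the list alone (camera adjusted p = 0.000505; adjusted p = 0.0547 with an estimated correlation). Tpx2, a spindle assembly factor, went from 441 ± 128 to 63.7 ± 22.2 CPM, and Cdc25c and Kif11 fell 8.42-fold and 6.12-fold. Ccna2 did not pass with TMM (log2 fold change -0.0083, SE 0.12) but fell under the oocyte scaling (-0.43). DNA replication genes had 17 of 35 lower and 10 higher, also adjusted over the list alone (camera adjusted p = 0.161, and adjusted p = 0.417 with an estimated correlation). Tyms was 7.98-fold and Rrm1 7.01-fold lower. The list median turned from -0.20 to 0.0018 with upper-quartile factors. The score per embryo fell by 0.685 (adjusted p = 1.4e-05, permutation test), with all 80 SR1848 embryos below the control median.

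Nuclear genes of oxidative phosphorylation fell in 51 of 76 cases and rose in 9, or 8 adjusted over the list alone (camera adjusted p = 1.1e-06; adjusted p = 0.148 with an estimated correlation). Cox6b1 fell 6.74-fold and Atp5a1 4-fold. Atp5b, the most abundant, had a log2 fold change of 0.30 that lost its call with RLE (relative log expression) factors, total counts and DESeq2 and was -0.14 under the oocyte scaling. Of 13 mitochondrially encoded genes 10 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.26; adjusted p = 0.769 with an estimated correlation), although 5 fell and 1 rose under the oocyte scaling. mt-Atp6 rose from 1852 ± 1211 to 5363 ± 4384 CPM, and mt-Cytb had a log2 fold change of 0.22 that did not pass (edgeR adjusted p = 0.163) but did with upper-quartile factors (0.44).

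Metabolic and stress lists moved in both directions. Glycolysis and pyruvate genes had 8 of 22 higher and 8 lower (camera adjusted p = 0.907; adjusted p = 0.938 with an estimated correlation), with the mitochondrial pyruvate carrier genes Mpc2 8.73-fold and Mpc1 2.32-fold lower and Ldhb 1.59-fold higher (log2 value -0.044 under the oocyte scaling). Cholesterol synthesis had 8 of 23 higher and 10 lower (camera adjusted p = 0.897; adjusted p = 0.899 with an estimated correlation), with Ebp 19.3-fold lower and Scap 3.11-fold higher. The p53 list had 6 of 16 higher and 6 lower (camera adjusted p = 0.843; adjusted p = 0.891 with an estimated correlation). Trp53 itself fell 4.06-fold and Mdm2 2.06-fold, and Plk2 rose from 64.7 ± 54.4 to 566 ± 319 CPM. The unfolded-protein and integrated stress response had 11 of 23 higher and 8 lower (camera adjusted p = 0.907; adjusted p = 0.938 with an estimated correlation). There the serine synthesis genes Psat1 and Phgdh fell 12.7-fold and 6.96-fold and Dnajb9 5.5-fold, while Herpud1 rose and Hspa5 (BiP) rose 1.48-fold, a call lost under the oocyte scaling (log2 fold change 0.17). Heat-shock genes had 11 of 20 higher and 7 lower (camera adjusted p = 0.375; adjusted p = 0.669 with an estimated correlation). Hspa1a rose from 21.9 ± 15.6 to 244 ± 261 CPM and Hsf1 3.14-fold, while Hsp90aa1 and Dnaja1 fell 1.74-fold and 2.52-fold. In these 5 lists the counts adjusted over the list alone were the same. For the glycolysis, p53 and stress response lists camera pointed down while their medians were slightly positive. Under the oocyte scaling the glycolysis list had 5 higher and 11 lower, cholesterol synthesis 5 and 13, the p53 list 2 and 8, the stress response 6 and 10 and the heat-shock genes 8 and 8. Medians of the glycolysis, p53 and stress response lists changed sign with total-count and oocyte scaling. Those of glycolysis (-0.023) and p53 (-0.037) also did so with RLE factors. The median of cholesterol synthesis changed sign with upper-quartile factors, and that of the heat-shock genes under the oocyte scaling. With TMM the score per embryo differed by 0.55 for heat-shock genes and by -0.41 for cholesterol synthesis (adjusted p = 1.4e-05 for each, permutation test). The stress response score differed by -0.26 (adjusted p = 0.0111) and the p53 score by -0.17 (0.0291) in that test. The glycolysis score (-0.10) did not pass (0.0834).

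Markers of other cells moved too. All 4 tested blood markers rose, also adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.0806 with an estimated correlation): the alpha-globin gene Hba-a2 stood at 30.1 ± 27.4 CPM in controls and at 155 ± 104 CPM with SR1848, and Hba-a1 at 13.8 ± 10.7 and 86.1 ± 63.5 CPM. The white-cell genes Srgn and Cd74 rose 2.36-fold and 1.89-fold, and Cd74 lost its call in embryos numbered above 40 (log2 fold change 1.04) and under the oocyte scaling (0.48). The globin genes are near-identical copies, and the beta-globin genes of the list did not reach the count filter. Of 23 cumulus and granulosa markers only 2 were tested, of which Bmpr1b rose 2.78-fold and Tnfaip6 fell 2.39-fold. Of 4 tested sperm transcripts Odf2, Tsga8 and Hspa1l rose and Ldhc fell, and in both lists the counts were the same adjusted over the list alone (sperm list: camera adjusted p = 0.38; adjusted p = 0.417 with an estimated correlation).

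Measured per embryo, 23 of the 27 list scores differed between the groups in a two-sided permutation test of 100000 resamples, 8 higher and 15 lower with SR1848. None of the scores was computed under the oocyte scaling, which moved the median log2 fold change of all genes from 0.24 to -0.35. Whether the smaller of the higher scores would stay higher with it is therefore open. For 7 lists (ribosome biogenesis, translation initiation, proteasome, splicing, RNA polymerase II, G2 and M phase, and the proposed activation regulators) all 80 SR1848 embryos were below every control. Treated embryos were also less alike. The mean absolute deviation from the group median was larger with SR1848 at an adjusted p under 0.05 in 15 lists and smaller in 1, while the other 11 did not pass. It was 0.505 against 0.182 for the unfolded-protein list (adjusted p = 9e-05) and 0.385 against 0.162 for heat-shock genes (adjusted p = 9e-05). For the G2 and M phase list it was 0.168 against 0.147 (adjusted p = 0.393).

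The deposited tables hold entries for the B1 and B2 families, short interspersed repeats (SINEs) transcribed by RNA polymerase III, and an entry under the Nr5a2 gene identifier beside the Nr5a2 transcripts. B1 rose from 40.8 ± 14.8 to 99.8 ± 51.2 CPM (2.44-fold, edgeR adjusted p = 1.9e-16) and B2 from 66.1 ± 43.7 to 222 ± 174 CPM (3.35-fold, adjusted p = 1.2e-15). The Nr5a2 gene-identifier entry stood at 37.8 ± 14.8 CPM in controls and 52.5 ± 29.3 CPM with SR1848 (log2 fold change 0.47, edgeR adjusted p = 0.00068), opposite to the Nr5a2 transcripts, and its value was -0.14 under the oocyte scaling. The GFP entries held at most 21 counts in any embryo, with counts in 16 and 16 SR1848 embryos and in 8 and 7 controls.

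**Figure D4:**
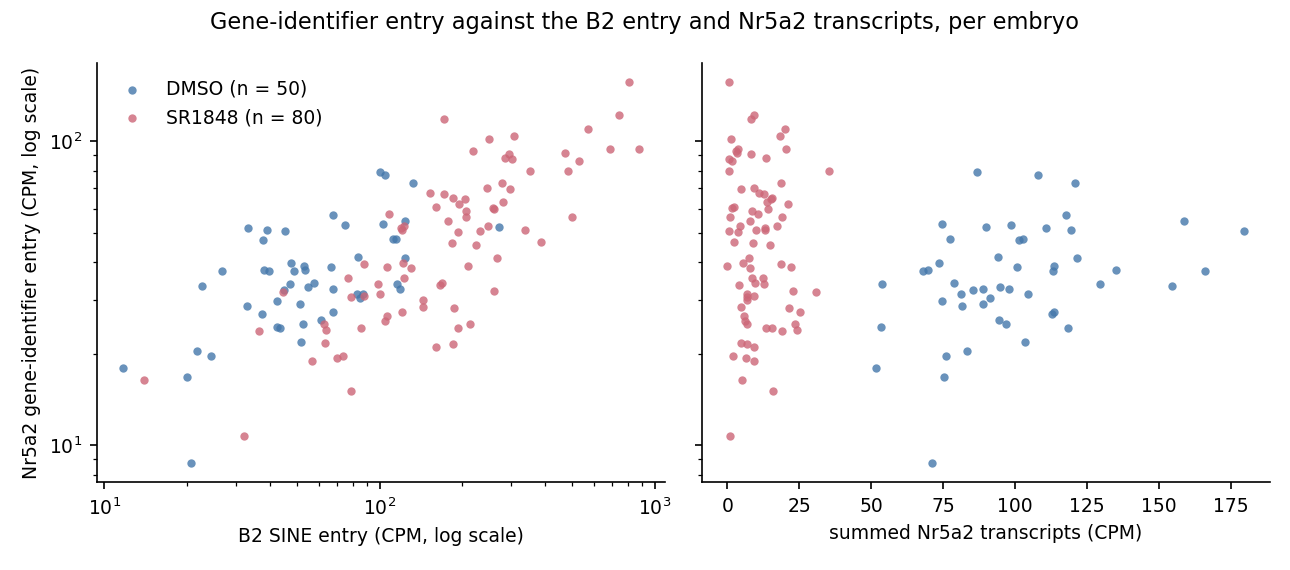
CPM of the Nr5a2 gene-identifier entry (log scale) against the B2 entry (left, log scale) and against the summed Nr5a2 transcripts (right, linear scale), with a point per embryo. Spearman's rho with B2 is 0.776 among 80 SR1848 embryos and 0.542 among 50 controls.

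The authors' deposited table of a DESeq2 comparison per transcript lists 12839 transcripts higher and 17559 lower with SR1848 at an adjusted p under 0.05, out of 66633 with an adjusted p. In the authors' deposited table B1 had a log2 fold change of 0.95, B2 of 1.43, and the Nr5a2 gene-identifier entry of 0.15 with an adjusted p of 0.358. Of 25761 transcripts also tested one by one here, 94.3% had the same direction in the authors' deposited table, and the 17122 past 0.05 in both all had the same direction. The balance differed, since the test here called 9930 transcripts higher and 9029 lower. Whether the authors' fit held the 6 controls not analysed here is not given.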

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

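The tests of depth, of embryo numbers, of repeats and of composition in this part were chosen after the results were seen, while those of retained introns, of the control embryos and of random splits were set before their results. The entry under the Nr5a2 gene identifier, which no gene comparison uses, was higher with SR1848 than in controls (log2 fold change 0.47), while the GFP entries were not above their level in controls. Of 100 splits of the 130 embryos into 80 and 50, 1, the real one, reached the 10861 changed genes found. The highest of the random others gave 73, which argues against chance as the source of that count. The splits treat embryos as independent, so they cannot separate SR1848 from handling shared by a whole group.

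B1, B2 and the Nr5a2 gene-identifier entry were higher with SR1848 although Nr5a2 transcripts fell. Among embryos of a group the gene-identifier entry followed B2, with Spearman's rho of 0.776 with SR1848 and 0.542 in controls (r = 0.762 and 0.514; 0.730 and 0.524 without the 2 embryos farthest in B2; adjusted permutation p at most 0.00046 over 6 relations). With Nr5a2 transcripts rho was -0.074 with SR1848 (adjusted p = 0.514) and 0.359 in controls (adjusted p = 0.0125). Retained-intron transcripts rose by a median of 0.45 log2 units more than coding transcripts of the same 1188 genes (quartiles -0.19 and 1.34), and their share of counts was 4.85 ± 1.46% against 4.18 ± 0.398% (adjusted p = 0.00259, permutation test). Reads from repeats or from unspliced or genomic sequence may therefore make up the gene-identifier signal, and a rise of SINE transcription itself was not tested and stays open beside them.

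Of 44 oocyte transcripts 36 rose and 4 fell (20 and 13 under the oocyte scaling; adjusted p = 0.378 with an estimated correlation). Of 28 genes of the 2-cell stage 22 rose (adjusted p = 0.37 with an estimated correlation), while most genes for translation initiation, the proteasome and splicing fell (adjusted p = 0.0432 with an estimated correlation for each). If the higher share of oocyte transcripts came from the loss of other messages alone, they would shift together. Their log2 fold changes instead had an SD of 0.85, 6.14 times their median SE of 0.139. Composition alone therefore does not give the differences between these genes. The test cannot decide on their common rise, since members that change on their own widen the SD whatever causes that rise. Among the 50 controls alone, slopes of 13178 other genes on the oocyte score correlated with the SR1848 fold changes across genes (rho = 0.535; with 1000 permutations of the control scores -0.399 to 0.466), although genes are not independent replicates. A delay of treated embryos along a course that controls also vary on may contribute, but a block of activation, a toxic effect of the compound and a delay were not separated, since no earlier stage and no inactive compound is among the samples.

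SR1848 embryos differed from each other more than controls did. Within the 80 SR1848 embryos the first component had a rho of 0.196 with log10 total count and the second a rho of -0.25 (adjusted p = 0.162 and 0.102), which argues against depth as the whole cause and leaves a smaller part open. Embryos with neighbouring numbers were alike on the second component, with a lag-1 correlation of 0.453 (adjusted p = 0.00016), and not on the first (-0.151, adjusted p = 0.241). In controls the lag-1 correlations were 0.238 and -0.021 (adjusted p = 0.187 and 0.886). Shared handling or library batches that follow the numbers may add to that second component, which holds 6.63% of the variance within the group. A varied response of single embryos stays open for the first, which holds 13.3%. The gene tests and permutation tests treat embryos as independent, and no fit blocked on runs of numbers. Where neighbours shared handling, the p-values of these tests may be too small.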

How the results depend on the processing

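Alternatives chosen after seeing the data were the oocyte scaling, the number ranges, leaving out multigene families and every other scaling of the B1, B2 and Nr5a2 gene-identifier entries. The count of changed genes stayed between 8363 and 11019 in all settings except no filter (17711 genes of 30065 tested; 10315 higher, 7396 lower, 7320 and 5405 at least 2-fold) and transcripts one by one (18959; 9930, 9029, 7014 and 7389), where more features were tested. The oocyte scaling gave 3422 higher, 1534 of them at least 2-fold, and significantly reversed 185 of the 10861 genes; it shifted the median log2 fold change of all genes from 0.24 to -0.35, RLE to 0.13, total counts to 0.05 and upper-quartile factors to 0.46. In embryos numbered up to 40 and above 40, 7763 of the 10861 genes were called in the same direction in both. The upper range is unbalanced, since control numbers end at 56 and SR1848 numbers run to 80. No pairing of SR1848 and control embryos by equal number was seen: deviations of the 50 same-numbered pairs correlated by 0.00622 on average. Of these pairs 2 were over 0.1, and 1 SR1848 embryo correlated best with the control of its own number. Neither this comparison nor the replicate block, which uses equal numbers, can decide on batches that span runs of numbers. With the replicate block 10093 genes changed, and no list changed its call.

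Of 2219 values for 139 named genes, 2178 kept direction and side of the threshold. Reversed were, under the oocyte scaling, Tmem92 -0.12, Tcl1 -0.047, Atp5b -0.14, mt-Nd6 -0.052, mt-Nd1 -0.17, mt-Co1 -0.20, Ldhb -0.044 and the Nr5a2 gene-identifier entry -0.14, and with upper-quartile factors Klf17 0.023. None of these reversed values passed the threshold (edgeR adjusted p at least 0.2075), so the calls were lost and no opposite change was called. The cause of these changes was not tested. Calls were lost under the oocyte scaling for Nr6a1, Scarb1, Nlrp5, Nlrp14, Rplp0, Hspa5 and Cd74. In embryos numbered above 40 they were lost for Klf17, Ccne1, Cd74, mt-Nd6, mt-Nd1 and mt-Co1. That range held only 55 of the 130 embryos, the smaller part of them controls, and each of these genes kept its direction there. Calls were gained for Eif5a, Psmd7, Fdft1 and Ccna2 under the oocyte scaling, and for Fdft1 also with total counts (-0.32), limma-voom (-0.33), detected genes as covariate (-0.28) and the replicate block (-0.46).

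With an estimated correlation 10 lists lost their call: 2-cell-stage genes 0.37, proposed regulators 0.0806, oocyte transcripts 0.378, subcortical complex 0.148, ribosomal proteins 0.381, ribosome biogenesis 0.0547, RNA polymerase II 0.0547, oxidative phosphorylation 0.148, G2 and M phase 0.0547 and blood markers 0.0806 (adjusted p). By fry, which compares no list with other genes, 10 more passed: pluripotency 6.4e-27, trophectoderm 3.8e-10, mitochondrially encoded 0.0128, glycolysis 0.0012, cholesterol 1.2e-05, p53 0.000823, stress response 0.0108, heat shock 1.2e-05, DNA replication 2.9e-23 and sperm 5.6e-11. Of the list scores, the mitochondrially encoded difference lost its call with RLE (0.254) and p53 with a prior count of 5 (-0.115), and glycolysis gained one (-0.126 with a prior count of 5, -0.216 with RLE), as did cumulus markers (0.371 with a prior count of 5). Spread differences passed with a prior count of 5 for nuclear receptors (0.0658), p53 (0.0918) and cumulus markers (-0.132), and that of blood markers was lost with it (-0.0795) and without 1 SR1848 embryo that was low in depth or detected genes (-0.165). The cause was not tested for these scores. Genes below the count filter were not tested. At these depths and this spread between embryos 46.3% of simulated 1.5-fold changes were recovered, and which of the 2 limits them was not tested. Only 200 of the 13222 simulated genes changed by design, while 82.1% of the genes tested changed in the real data. A threshold adjusted over all genes is stricter where few genes change, so this rate does not carry over to the real comparison.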

Other observations

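The gene families and the tests of gene span and single-exon genes in this part were chosen after the results were seen. Histone genes were among the most uniform risers: 45 of 51 tested rose and 3 fell (camera adjusted p = 5.2e-09; adjusted p = 0.00756 with an estimated correlation), H2ax from 22.2 ± 13.4 to 238 ± 210 CPM and H1f0 from 36 ± 23.1 to 161 ± 112 CPM, while the replacement genes H3f3a (log2 fold change -1.26) and H2az2 (-2.06) fell and their paralogs H3f3b (0.38) and H2az1 (0.37) rose with TMM, which was not examined under other scalings. Of 50 tested genes from chosen groups of homeobox, SOX and bHLH factors, such as Hox, Lhx, Sox, Hes and Id, 41 rose and 3 fell. Their camera adjusted p was 9.5e-09, and 0.0163 with an estimated correlation. Hey1, Id1 and Isl2 reached log2 values of 4.05, 2.69 and 3.76. Homeobox genes of the fixed lists such as Nanog, Pou5f1, Duxf3 and the Obox genes were not in this family. Its share of rising genes therefore does not describe the whole class. Of 18 immediate-early genes 17 rose (camera adjusted p = 2.2e-05; adjusted p = 0.0537 with an estimated correlation), including Dusp6 from 16.8 ± 16.3 to 241 ± 139 CPM and Egr1 (2.24). With the oocyte scaling 41 histone genes, 36 factor genes and 17 immediate-early genes rose. Oligo-dT priming mainly captures messages with a poly(A) tail, so the histone values need not follow all histone messages. The count filter also shaped these counts. Members near 0 in controls, such as H2ac23 (0 CPM), H2bc14 (0.088), Sox17 (0.064) and Atoh1 (0.040), passed it only through SR1848 embryos. Such members could not be called lower, so the shares of rising genes partly follow from the filter.

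Falling families outside the fixed lists were mitochondrial ribosomal proteins (57 of 78 lower, 12 higher; camera adjusted p = 3.5e-05; adjusted p = 0.0537 with an estimated correlation), mitochondrial import subunits (16 of 23 lower, 4 higher; 0.000571; adjusted p = 0.0268 with an estimated correlation), aminoacyl-tRNA synthetases (20 of 31 lower, 5 higher; 0.00707; adjusted p = 0.0537 with an estimated correlation), chaperonin subunits (8 of 9 lower, 1 higher; 0.00364; adjusted p = 0.0537 with an estimated correlation) and nucleoporins (14 of 21 lower, 4 higher; 0.0101; adjusted p = 0.0537 with an estimated correlation). Of 46 Pramel genes 30 rose and 13 fell (camera adjusted p = 0.0211; adjusted p = 0.353 with an estimated correlation). Of 109 olfactory receptor genes 90 rose and 5 fell (camera adjusted p = 1.7e-07; adjusted p = 0.098 with an estimated correlation), and 60 rose and 7 fell under the oocyte scaling. Olfr624 stood at 13129 ± 3424 CPM in controls and 24750 ± 9549 CPM with SR1848, and Olfr1173, Olfr639 and Olfr472 had log2 fold changes of 0.95, 0.87 and 0.91; reads shared between copies were not separated here.

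Short genes such as Hes1, Jun and Msx1 stand among the largest rises, so a fall of fold change with gene span was tested across 13185 genes. Spearman's rho was 0.0483, which argues against a trend with length over the whole transcriptome. The 170 protein-coding genes that rose at least 8-fold were still short, with a median span of 3.15 kb against 24.9 kb for the 12336 tested and 19.4 kb for the 520 that fell at least 8-fold. The shorter span did not extend to the 3393 that rose at least 2-fold (median 26.97 kb) against the 3219 that fell at least 2-fold (21.2 kb). Genes with a single exon were still 4.57% of these 3393 and 1.21% of these 3219. Single-exon genes made up 27.6% of the 170 and 2.42% of all tested (Fisher's exact test, two-sided, p = 5.3e-37, not corrected). The test treats genes as independent, while histone genes such as H2ax (log2 fold change 3.42) and H3c8 (4.89), of a family that rose together, passed 8-fold. The share without histone genes was not computed.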
